A study of Mus musculus with 2 samples.

How the data were processed

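Each of the 2 libraries held single-cell 3' gene expression counts from mouse bone marrow cells sorted as natural killer progenitors (NKP), 1 from wild-type mice and 1 from Irf4-/- mice. Per the labels, the gate took cells negative for lineage markers, Sca-1, c-kit, NK1.1 and Ncr1 and positive for CD122, the protein product of Il2rb. Libraries were made with a droplet 3' kit, per the labels' protocols, whose kit text speaks of nuclei while the sort was of cells. The deposited values are whole-number UMI counts per gene and barcode, made by Cell Ranger 6.1.1 per the file headers, with the mm10 build per the submitters' processing notes. The annotation release is not given in the sources used here. A 3' library counts mostly transcript ends, and the part of Irf4 that the allele lacks is not given in the sources used here, so an Irf4 count need not test the genotype. Positions of reads were not used here.

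A barcode was kept with at least 500 detected genes, at least 1000 UMIs and under 10% of UMIs from mitochondrial-encoded genes. This left 7955 of 8147 barcodes of the library labelled Irf4-/- and 12367 of 12732 of the library labelled WT. Median depth was 9540 and 7125 UMIs per kept cell. Scrublet called 3 and 0 doublets, under 0.5% of kept cells, so the caller did not work on these libraries and no doublets were removed. Cluster 15, of 99 and 112 cells with a median depth of 11394 UMIs, had Cd79a in 99.5% and Cd3d in 90.05% of cells, as doublets of B and T cells would, and was kept in all values over all cells. Cells of both libraries were scaled to 10000 UMIs, log-transformed and clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1 with igraph 0.11.9).

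A cluster was called X-like only from 19 marker sets fixed before the data were examined. At least 2 markers had to be among its 10 leading genes by fold and detected in at least 40% of its cells, with at least 3 markers detected in at least 25%. Natural killer and innate lymphoid names were removed where all CD3 genes were detected in at least 50% of cells, and dendritic names where Cd79a was. The smaller B-like cluster, led by H2-Aa and H2-Eb1, was named by the Cd79a rule. A cluster with both CD3 genes and Cd79a in at least 50% of cells stayed unnamed. These numeric limits and removals were set after the clusters were seen. Clusters that matched no set, or 3 or more, stayed unnamed, and of 2 sets the one with more leading markers gave the name. Unnamed clusters held 61.6% and 48.0% of kept cells in the libraries labelled Irf4-/- and WT. The partition of the T cell clusters, named and unnamed, changed with the random seed and with the number of processor threads, which were therefore fixed. Over 5 other seeds the best match of the cluster led by Klre1 kept between 43.1% and 84.4% of its cells, and that of the cluster led by Klra3 between 35.8% and 89.9%. Of the alpha-beta T-like clusters, cluster 1 kept between 50.2% and 85.6% and cluster 7 between 63.3% and 73.4%, while the class as a whole kept between 89.0% and 92.8% of its cells. Unnamed T cell clusters are therefore not compared one by one. In their place the 13 clusters with all 3 CD3 genes in at least 50% of cells and Cd79a in under 50% were pooled, and the 9 unnamed ones of these were pooled as well, both choices made after seeing the data.

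Counts were summed per library and population. The log2 ratio of CPM, library labelled Irf4-/- over library labelled WT, was given with an exact conditional binomial 95% interval. CPM has an exact Poisson interval and a share of cells an exact Clopper-Pearson interval. These intervals cover counting error only. The interval of a median over genes, used to compare alternatives and to flag lists, came from the ranked ratios of its members. With 1 library per genotype there was no replicate check, so no test was made and no number of altered genes is given. Where a library had no count, the ratio used a floor of 3 counts. For each of 23 gene lists the median over members with at least 20 UMIs was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. For shares of cells with a UMI and for phase scores, cells were thinned to 2000 UMIs, which left out 35 and 71 shallower cells.

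Named genes followed a rule fixed at the same time as the marker sets. It took Irf4 and the genes of the gate, the 12 highest and 12 lowest ratios of the main class, the 10 highest and 10 lowest over all kept cells, and the 3 highest and 3 lowest of other classes with at least 200 cells in each library. Genes taken by rank had a mean of at least 50 CPM, a minimum that did not apply to Irf4, the gate genes or list members. Up to 4 members of each list with the largest ratios were added. Not every gene that the rule names is reported here. Predicted genes, mitochondrial-encoded, ribosomal protein, receptor segment, immunoglobulin and haemoglobin genes, and genes that mark sex were left out. The clusters led by Klre1 (1573 and 796 cells) and by Gzmk (0 and 296) met the limits for a natural killer name. Both lost it by the CD3 removal, which was set after the clusters were seen. Without that removal they would have been the main class under the rule, which needed at least 200 cells in each library. With no natural killer-like class left, the main class was the alpha-beta T-like one, by the same rule. Coordinates are from GENCODE vM21 on GRCm38, the assembly of mm10.

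The computation of ratios and intervals was tested on simulated counts for all kept cells, with 200 of 2309 genes altered. Intervals held the true value for 94.8% of unaltered genes and for between 88.2% and 97.1% of genes at each altered size. The simulated counts were independent draws per gene, without clumping of UMIs in single cells. They check the computation and not the coverage in these data. Alternatives covered the cell filter, the doublet score, the scaling (including TMM from edgeR 4.0.16 in R 4.3.3), the clustering and its seed, the weighting of cells, the list minimum and the thinning depth.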

Results

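Single-cell RNA counts were collected from bone marrow NKP cells, sorted precursors of natural killer cells, of wild-type C57BL/6 mice and of mice lacking Irf4, a transcription factor of lymphocyte activation and plasma cell formation. There was 1 library per genotype. The library labelled Irf4-/- held 82599767 UMIs and the library labelled WT 95031071. The comparison asks how the sorted cells differ between the genotypes.

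Irf4 was not lower in the library labelled Irf4-/-. Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976) had 803 UMIs there, 9.77 CPM with an interval of 9.11 to 10.5. In the library labelled WT it had 287 UMIs, 3.04 CPM with an interval of 2.70 to 3.41. The log2 ratio was 1.68, with an interval of 1.49 to 1.88. Within the B-like class the counts were 225 and 105 UMIs, a log2 ratio of 0.95, and within its larger cluster 209 and 86 UMIs, a log2 ratio of 0.62 with an interval of 0.25 to 0.99. Within its smaller cluster they were 16 and 19 UMIs. Within the progenitor B-like class they were 322 and 53 UMIs, a log2 ratio of 0.57. The alpha-beta T-like class had 26 and 20 UMIs and a log2 ratio of 1.85. A 3' count outside the deleted part checks nothing, and the deleted part is not given in the sources used here. The genotype labels were therefore neither borne out nor excluded by Irf4, and every direction below is between libraries as labelled.

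Most cells of both libraries carried T cell transcripts, although the gate was for natural killer progenitors. The 13 CD3-expressing clusters held 84.7% of kept cells in the library labelled Irf4-/- (interval 83.9% to 85.5%) and 90.7% in the library labelled WT (interval 90.2% to 91.2%). Cd3d, a subunit of the T cell receptor complex, had a UMI in 86.1% and 87.2% of those cells after thinning, and in 99.5% and 99.4% before it. In the B-like class, which should lack Cd3d, the thinned shares were 2.28% and 8.89% and those before thinning 4.27% and 11.8%, at median depths of 4122 and 3072 UMIs against 9916 and 7244.5 in the CD3-expressing clusters. Il2rb, the gate's positive marker, was detected in 52.3% and 42.6% of cells in the CD3-expressing clusters after thinning, and in 1.75% and 2.47% of B-like cells. Before thinning these were 93.2% and 80.3%, and 2.94% and 6.46%. Ncr1, a natural killer receptor gated out, had 65 and 19 UMIs. Klrb1c, which encodes NK1.1, had 1358 and 854, Kit 146 and 77, and Ly6a, which encodes Sca-1, 517 and 453. No cluster met the markers of natural killer cells or of early innate lymphoid progenitors without CD3.

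The Cd8b1-led clusters, named alpha-beta T-like, made up a smaller share of the library labelled Irf4-/-. This class is only a part of the cells with alpha-beta receptor transcripts, since Trac and Trbc2 were each detected in at least 85.9% of cells of each of 9 unnamed CD3-expressing clusters. Those clusters together held 59.6% and 46.6% of cells. The alpha-beta T-like cells were 14.4% of its cells (1145, interval 13.6% to 15.2%) against 34.6% of the library labelled WT (4279, interval 33.8% to 35.4%). Cd8b1, among the leading genes of each of these clusters, and Dapl1, among those of 2 of them, themselves differed between the libraries. When the cells were clustered without the Klr genes and the leading genes of 3 T cell clusters, the shares were 13.6% and 30.3%, a log2 ratio of -1.15 against -1.27 with them. Clusters there were still named from the full marker sets, with Cd8a and Cd8b1, so those genes could still decide the class. With the highest marker score per cell, which uses them too, the shares were 18.8% and 32.1%. Progenitor B-like cells, led by Vpreb1 and Ebf1, were 3.61% and 0.881%. B-like cells were 9.42% and 6.76%, but none were named in the library labelled Irf4-/- when each library was clustered on its own. Gamma-delta T-like cells were 10.7% and 9.53%, and the direction of this difference changed with the clustering. The gate removed lineage-positive cells, so the sort itself can set all of these shares.

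**Figure D1:**
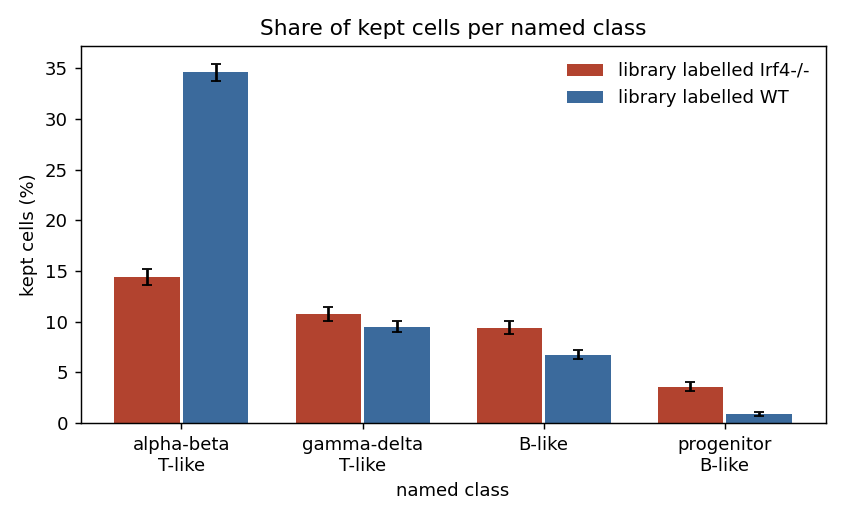
Share of kept cells (%, vertical axis) in each named class (horizontal axis) in the library labelled Irf4-/- (red) and the library labelled WT (blue), with bars as exact binomial 95% intervals for counting error. Alpha-beta T-like cells were 14.4% and 34.6%.

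Over all kept cells, natural killer receptor genes, cell cycle genes and B progenitor genes were higher in the library labelled Irf4-/-, and Cd8b1, Dapl1, Il7r and Ccr7 were lower. Klre1 (log2 ratio 1.40, interval 1.35 to 1.45) and Klrc2 (1.31) encode lectin-like natural killer receptors, and Xcl1 (1.18) is a chemokine. Pim2, a survival kinase, had 1.19 and Hist1h2ap, a histone gene of dividing cells, 1.36. Vpreb3 (1.39), Ebf1 (1.24) and Cd24a (1.43) are expressed in B progenitors. Within the CD3-expressing clusters Klre1 had 1.47, Klrc2 1.37, Pim2 1.28, Xcl1 1.24 and Hist1h2ap 1.23, while Vpreb3 had 0.34 and Ebf1 0.51. The libraries filled these clusters differently, with 19.8% and 6.44% of cells in the cluster led by Klre1, Klrk1 and Klrc2, and 7.29% and 21.4% in cluster 1. With the 12 of these clusters that had cells in both libraries reweighted, Klre1 had 0.68, Klrc2 0.64, Pim2 1.12, Xcl1 0.75 and Hist1h2ap 0.20, and Vpreb3 and Ebf1 turned to -0.45 and -0.46. Klre1, Klrc2, Xcl1 and Hist1h2ap are leading genes of clusters held fixed there, so the reweighting can itself shrink their ratios. Among the lowest were Cd8b1 (-1.13), Dapl1 (-1.08), Fam169b (-0.87), Il7r, the interleukin-7 receptor (-0.86), Pik3ip1 (-0.82), Slfn1 (-0.81) and Ccr7, a lymph node homing receptor (-0.74). Of these, Cd8b1, Dapl1, Fam169b and Ccr7 are leading genes of cluster 1, the smaller share in the library labelled Irf4-/-. Within the alpha-beta T-like class Cd8b1 had -0.21 and Dapl1 -0.48. Both are leading genes of clusters in that class, so its selection can itself make these ratios smaller. Themis (-0.49), Grap2 (-0.48) and Cd5 (-0.48), genes of T cell receptor signalling, followed. S100a8 and S100a9, neutrophil genes, had 2.66 and 2.38, but without the myeloid cluster of 64 and 59 cells S100a8 had -0.33 and S100a9 0.14.

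The natural killer receptor list had a median log2 ratio of 0.77 over all kept cells (22 members, 21 above 0, percentile 100 of the random lists). S phase genes had a median of 0.64 and G2 and M phase genes 0.97, with Uhrf1 at 1.14 and Aurkb at 1.15. MHC class II had 0.68, but B cell markers (0.58, 9 of 11 above 0) and progenitor B cell markers (1.97) were higher as well. MHC class II had 0.58 in the CD3-expressing clusters (8 of 11 above 0), 0.22 in B-like cells and -0.29 in gamma-delta T-like cells, over 4 members. It had -0.38 in alpha-beta T-like cells, over 5 members. The CD3-expressing clusters include that led by Hist1h2ap, with Cd79a in 18.2% of its cells, so 0.58 need not be a value of T cells. MHC class I, led by H2-Q7 at 0.50, had 0.33 with 14 of 14 members above 0. Cytokines and chemokines had 0.49, with Csf2 at 2.86. Type I interferon response genes had 0.24, with Oas1a at 1.37, Ifi44 at 1.27, Oas2 at 1.09 and Ifit3 at -7.19. Nuclear-encoded oxidative phosphorylation had 0.20, mitochondrial-encoded genes 0.17, glycolysis 0.13, nutrient transport 0.13 and immediate-early genes 0.17. The glycolysis value was smaller under other scalings, given below. Pro-apoptotic factors had 0.17, with Cdkn1a at 1.85 and Bbc3 at -1.13, and pro-survival factors 0.09. Cytokine receptors and JAK-STAT genes had 0.12, with Socs2 at 1.83. IRF4 partners and targets had 0.17, interferon regulatory factors 0.12, homing genes 0.09, cytotoxic effectors 0.08, early natural killer maturation 0.06, ribosome biogenesis 0.01, innate lymphoid transcription factors -0.03 and late natural killer maturation -0.10. The random lists had medians of 0.03 to 0.05.

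In the alpha-beta T-like class, the main class, the cells of the library labelled Irf4-/- had more Xcl1, Id2 and Ifi27l2a transcript and less Itga4 and Il7r. Xcl1 had a log2 ratio of 1.02 (interval 0.91 to 1.13), Id2, a regulator of innate lymphoid and memory T cells, 0.75, and the interferon-induced Ifi27l2a 0.62. S100a6 (0.58), Ost4 (0.56), Polr2l (0.53), Socs1, an inhibitor of cytokine signalling (0.51), Hopx (0.50), Uqcc2 (0.49), Jaml (0.47), Itgal (0.45) and Tmem108 (0.45) completed the highest 12. Itga4, an integrin subunit, had -0.91 (interval -1.03 to -0.79), Atp1b1 -0.77, Btg2 -0.60 and Il7r -0.55 (interval -0.60 to -0.51). Cdkn1b, a cell cycle inhibitor, and Pik3ip1 both had -0.52. Il18r1 and Zbtb20 had -0.51, Dapl1 and Tent5a -0.48, Stk38 -0.46 and Smc4 -0.45. This class joined clusters 1, 6 and 7 in different proportions, 580, 373 and 192 cells in the library labelled Irf4-/- and 2652, 745 and 882 in the library labelled WT. With the clusters reweighted, Xcl1 had 0.88, Id2 0.55, Ifi27l2a 0.72, Itga4 -0.71, Il7r -0.53 and Dapl1 -0.25, and S100a6 only 0.067.

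All 24 genes had the same sign in gamma-delta T-like cells, and 23 of 24, all but Il18r1, in the unnamed CD3-expressing clusters, which hold no cell of the class. Every class comes from the same 2 libraries, so a difference between the libraries as a whole would also give the same signs. Median depth differed in both classes, with 11074 and 7941 UMIs in alpha-beta T-like cells and 8378 and 5652 in gamma-delta T-like cells. Of gamma-delta T-like cells 54.5% and 44.9% had a Trav or Trbv UMI, against 64.7% and 56.5% of alpha-beta T-like cells. This count took in segments shared with the delta chain, such as Trav13-4-dv7, a leading gene of the gamma-delta T-like cluster. The shares therefore do not show alpha-beta receptor use in gamma-delta T-like cells. In B-like cells 8 of 24 had the other sign, among them Xcl1 (-0.42), S100a6 (-0.71) and Itgal (-0.82). In gamma-delta T-like cells Xcl1 had 0.99, Id2 0.94, Ifi27l2a 1.05, Il7r -0.79 and Itga4 -0.42. In the unnamed CD3-expressing clusters Xcl1 had 0.94, Il7r -0.87, Itga4 -0.61 and Il18r1 0.021. Of their cells, 1573 of 4738 and 796 of 5761 lay in the cluster led by Klre1, which Xcl1 leads too. With the 8 of these clusters that had cells in both libraries reweighted, Xcl1 had 0.69, Il7r -0.73, Itga4 -0.40 and Il18r1 -0.12, and 24 of 24 genes had the sign of the class.

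**Figure D2:**
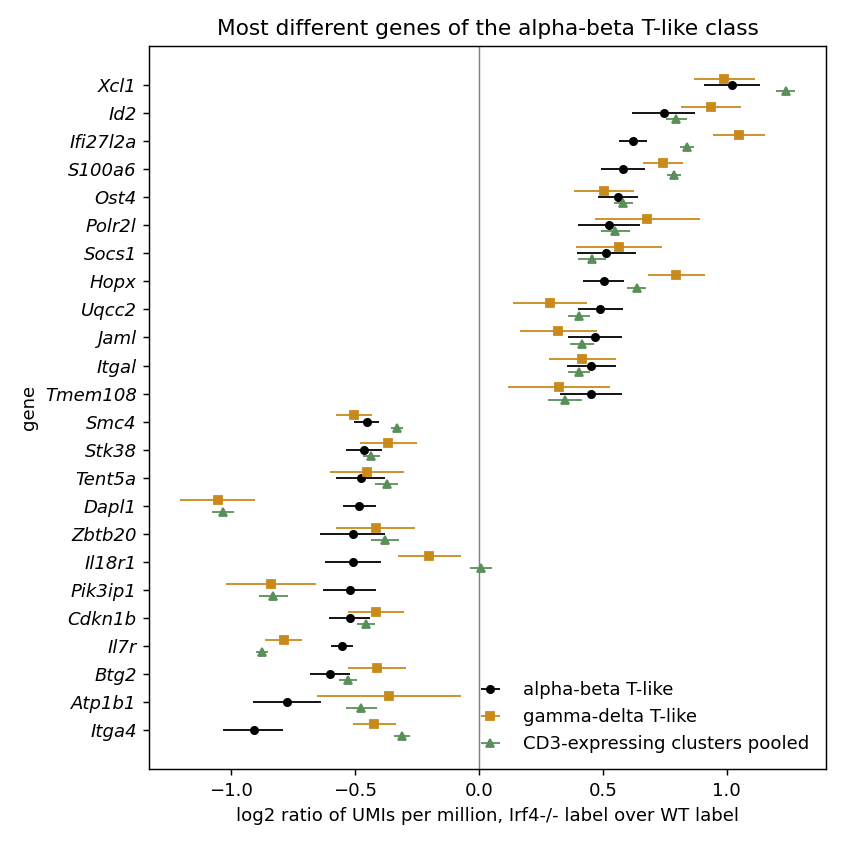
Log2 ratio of CPM, library labelled Irf4-/- over library labelled WT (horizontal axis), of the 12 highest and 12 lowest genes of the alpha-beta T-like class (vertical axis), with bars as 95% counting intervals. Xcl1 had 1.02 and Itga4 -0.91 in that class (circles); squares are gamma-delta T-like cells and triangles all CD3-expressing clusters, which include the alpha-beta T-like class.

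Of the lists in the alpha-beta T-like class, natural killer receptors had a median of 0.53 (20 members, 18 above 0), with Klre1 at 1.54 and Klrc1 at 1.17. Cytokines and chemokines had 0.35, type I interferon response 0.32, and MHC class I 0.24 with 14 of 14 members above 0. Of the interferon genes Oas1a had 1.80, Usp18 1.39 and Ifit2 -1.40, and Ifit3 had 1 UMI against 408, a log2 ratio of -7.20 with an interval of -12.51 to -4.72. MHC class II had -0.38 over 5 members. S phase genes had 0.12, but G2 and M phase genes -0.25 (30 members, 21 below 0). Clusters led by cell cycle genes lie outside this class, and over all CD3-expressing clusters G2 and M phase genes had 0.82. In the alpha-beta T-like class some of their counts were low, with 2 and 19 UMIs of Nusap1 and 14 and 75 of Mki67. The value of -0.25 is therefore not a measure of cycling among all alpha-beta T cells. Mitochondrial-encoded genes had 0.16, late natural killer maturation 0.14, cytokine receptors 0.14, cytotoxic effectors 0.12, oxidative phosphorylation 0.12, pro-survival factors 0.11, with Pim2 at 0.71, glycolysis 0.10, nutrient transport 0.10, pro-apoptotic factors 0.09, homing 0.05, ribosome biogenesis 0.04, early maturation 0.02 and immediate-early genes -0.03. Innate lymphoid transcription factors had -0.0045, IRF4 partners and targets -0.00075 and interferon regulatory factors 7.8e-05. The random lists had medians of -0.05 to 0.0021.

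In gamma-delta T-like cells Pim2 (1.33) and Klre1 (1.31) were among the highest genes, and the lowest were Dapl1 (-1.05), Id3 (-0.98) and Myb (-0.93). In B-like cells the highest were Wnt10a (2.04), Ifi27l2a (1.41) and Bcl2a1b (1.36). The lowest were Cd3d (-2.02), Bcl2 (-1.86) and Cd3g (-1.85), of which the CD3 genes are T cell transcripts. This class joined 2 clusters in different proportions, 637 and 112 cells in the library labelled Irf4-/- and 513 and 323 in the library labelled WT. In the larger cluster, led by Ms4a1, Wnt10a had 1.53, Ifi27l2a 1.20, Bcl2a1b 1.70, Cd3d -0.92, Bcl2 -1.78 and Cd3g -0.90. In the smaller one Wnt10a had 5 and 2 UMIs, Ifi27l2a had 1.23, Bcl2a1b 0.57 (interval -0.078 to 1.20), Cd3d -1.45, Bcl2 -0.90 and Cd3g -1.15.

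After thinning, the share of cells with an S or G2/M score above control genes was 38.1% (interval 37.0% to 39.2%) in the library labelled Irf4-/- and 36.3% (interval 35.5% to 37.2%) in the library labelled WT. It was 30.1% and 29.5% without thinning. In B-like cells it was 20.03% and 26.9%. Clusters led by cell cycle genes were larger shares of the library labelled Irf4-/-. The cluster led by Hells and Mcm3 held 4.34% and 1.46% of cells, that led by Hist1h2ap 2.88% and 1.48%, and that led by Cenpf 1.16% and 0.598%. Phase scores read free RNA too, and no cycling is read from them.

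Ifit3 and the adjacent Ifit1bl1, interferon-induced genes, were almost without counts in the library labelled Irf4-/-. Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) had 16 UMIs against 2687, a log2 ratio of -7.19 with an interval of -8.00 to -6.49. Ifit1bl1 (chromosome 19, 34592891 to 34601956), singled out after its values were seen, had 0 against 2768 UMIs, at least 804-fold lower. The neighbours Ifit2 (673 and 1577 UMIs), Ifit3b (627 and 501) and Ifit1 (1114 and 1815) were counted in both libraries. Ifit genes are paralogs, and their counts can share reads.

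**Figure D3:**
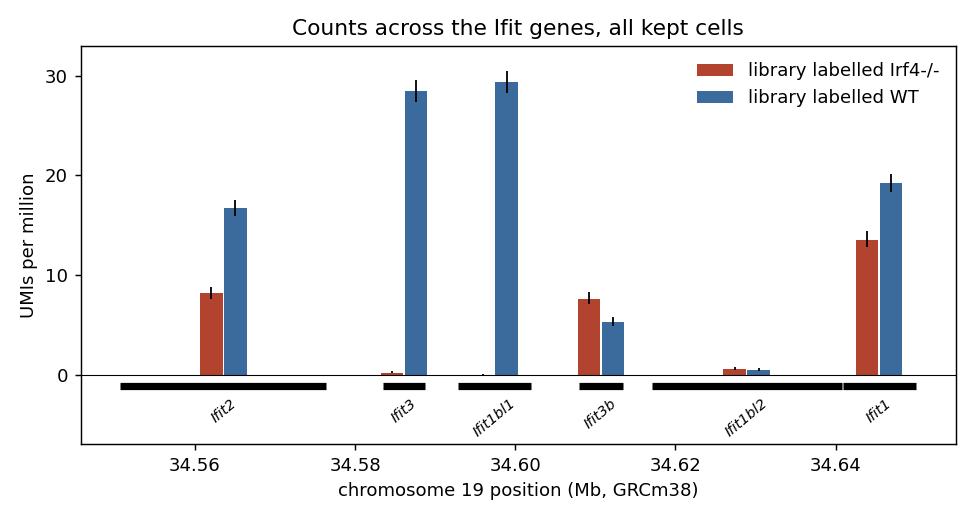
CPM (vertical axis) of the Ifit genes in all kept cells along chromosome 19 (horizontal axis, Mb), library labelled Irf4-/- in red and library labelled WT in blue, with 95% Poisson intervals and gene extents as black bars. Ifit3 had 16 UMIs and Ifit1bl1 0 in the library labelled Irf4-/-, against 2687 and 2768.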

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

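The comparison of classes here was chosen after the values were seen. The natural killer receptor list had a median log2 ratio of -1.29 in B-like cells, against 0.53 in alpha-beta T-like cells and 0.65 in gamma-delta T-like cells. The glycolysis list had -0.16 in B-like cells and 0.09 in gamma-delta T-like cells. In B-like cells the markers of other cell types were lower too, with medians of -1.88 for alpha-beta T cells, -1.24 for gamma-delta T cells and -1.60 for the natural killer and ILC1 lineage. Both were picked out because the directions were opposite between classes, and neither difference was tested. Klre1, a member of the first list, had a UMI in 0.403% and 0.617% of thinned B-like cells, against 20.2% and 8.13% in the CD3-expressing clusters.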

How the results depend on the processing

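The alternatives chosen after seeing the data were other seeds, removal of the highest Scrublet scores, clustering without Klr and defining genes, the CD3-expressing denominator, removal of the myeloid cluster, reweighted CD3-expressing clusters and the Irf4 ratio within classes and clusters; the others were planned. Where the interval of a result excluded 0 and an alternative gave a ratio, directions were kept in all but 5 cases, the share of gamma-delta T-like cells under 2 settings, S100a8, Vpreb3 and Ebf1. When each library was clustered on its own, no ratio was obtained for 2 further classes. Cells named B-like were then 0% and 8.41%, and cells named progenitor B-like 3.38% and 0%. These zeros come from the naming and need not mean absent cells, so no direction is read from them. Unnamed cells were then 75.5% of the library labelled Irf4-/-, and Cd79a had a UMI in 15.6% of its kept cells. No erythroid-like ratio was obtained with each library clustered on its own or at resolution 0.5. The cause of each shift below was not tested.

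The percent of barcodes kept in the library labelled Irf4-/- was 96.9% with the stricter filter, 86.2% with the mitochondrial limit of 5% and 93.2% without the highest Scrublet scores. In the library labelled WT these were 95.6%, 93.3% and 92.4%, and 97.6% with the looser filter. The Irf4 log2 ratio was 0.95 within B-like cells, 0.62 and 1.05 within their larger and smaller clusters, and 0.57 within progenitor B-like cells.

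The log2 ratio of the share of cells, alpha-beta T-like, was -0.77 with the highest marker score per cell, where 5504 of 20322 cells lay within 0.1 of the next type. It was -1.15 without Klr and defining genes, -1.38 with seed 4 and -1.17 over CD3-expressing cells. The log2 ratio of the share of cells, gamma-delta T-like, reversed to -0.19 when each library was clustered on its own and to -0.013 with seed 4. It was 0.041 without cell cycle genes, 0.030 with seed 5 and 0.033 with seed 6. The log2 ratio of the share of cells, B-like, was 0.32 without Klr and defining genes and with seed 2, 0.33 with seed 6 and 0.30 with the mitochondrial limit of 5%. The log2 ratio of the share of cells, progenitor B-like, was 2.39 without Klr and defining genes, 2.42 with seeds 2 and 6, 2.40 with seed 4 and 2.37 with seed 5. The log2 ratio of the share of cells, erythroid-like, was -1.19 with the highest marker score.

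S100a8 reversed to -0.33 without the myeloid cluster. With CD3-expressing clusters reweighted, Vpreb3 in all of these clusters reversed to -0.45 and Ebf1 to -0.46. With clusters reweighted, the median of the 12 lowest alpha-beta T-like genes was -0.47 and that of the 12 highest 0.46. S phase genes over all kept cells had 0.47 with the mean of per-cell CPM. The median log2 ratio, glycolysis, all kept cells was 0.081 with TMM scaling and 0.069 with the scaling that left out mitochondrial, ribosomal, haemoglobin and immunoglobulin genes. It was 0.071 with the mean of per-cell CPM. The median log2 ratio, ribosome biogenesis, all kept cells was -0.053 with that scaling. With thinning, the log2 ratio of the share of cells above control genes for S or G2/M, gamma-delta T-like, was 0.074 (35.5% and 33.7%, interval -0.15 to 0.29) but turned to -0.36 without thinning (22.8% and 29.2%). Of the values for gene lists under alternatives, 363 stayed within the main interval and 5 did not. That interval is the spread over member genes and can be wide, as for late natural killer maturation over all kept cells (-0.86 to 0.96). Staying within it therefore says little about stability.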

Other observations

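All tests in this part were chosen after the result was seen. Of the genes named here, Xlr3b, Ccl1, Maf, Lag3 and Havcr2 were chosen after their values were seen. Gzmk, a granzyme of effector memory T cells, had 1 UMI in the library labelled Irf4-/- and 721 in the library labelled WT, of which 160 lay outside the cluster it leads. Its log2 ratio was -9.29 with a counting interval of -14.60 to -6.81. That cluster, with Gzmk, Maf, Lag3 and Havcr2, held 0 of 7955 cells, which allows up to 0.0464%, and 296 of 12367. Over 5 other seeds its best match held between 1 and 54 cells of the library labelled Irf4-/- and between 294 and 482 of the library labelled WT. Csf2 had 360 and 57 UMIs over 302 and 54 cells, and Xlr3b 28 and 340 over 24 and 307 cells. The ratios of Igha, Jchain and Ccl1 rested on single cells. Of 607 Igha UMIs in the library labelled WT 591 came from 1 cell, as did 358 of 371 Jchain UMIs, and all 166 Ccl1 UMIs of the library labelled Irf4-/- came from 1 cell.

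CD3 and T cell receptor transcripts filled libraries sorted as natural killer progenitors. Free RNA would mix receptor segments, but over all kept cells with at least 2 Trbv UMIs (1125 and 1222) cells held 1 segment at least 15.3 times as often as draws from the pool. For cells with under 2 Trbv UMIs, free RNA would give a like share with Cd3d to all cell types. At equal depth that share was 11.2% and 18.7% in cells with a Cd79a UMI but 85.8% and 86.8% in cells without one. Without cluster 15, which held CD3 genes and Cd79a together, the first 2 shares were 7.32% and 14.0%. Thus free RNA is argued against as the main source there too. This test replaced an earlier one that left free RNA open, in which Cd3d in CPM was 4.22-fold and 2.83-fold higher in cells without a Cd79a UMI, short of a bound of 5-fold. Doublets with CD3-negative progenitors would leave unpaired progenitors, with no CD3 or receptor constant UMI. Outside the B-lineage, myeloid and erythroid clusters such cells were 15 and 25, at most 0.311% of kept cells by the upper bound. All of them lay in the CD3-expressing clusters, which were chosen for CD3 genes, so a low share was partly built in. Unpaired progenitors within the B-lineage, myeloid and erythroid clusters were not counted. Doublets with CD3-negative progenitors therefore stay open. Unrearranged transcription that mixed segments within a cell is argued against by nearly the same cells as free RNA, those with at least 2 Trbv UMIs. In the CD3-expressing clusters 76.2% and 72.0% of cells with at least 2 Trbv UMIs held 1 segment. Draws gave 4.73% and 4.68%, a ratio of at least 15.4. The rest of these cells held more than 1 segment. This covered 1112 of 6738 and 1200 of 11218 cells, and the others were not tested. Counts per gene do not show joining, so unrearranged transcription of 1 segment per cell stays open. A hypothesis is that many sorted cells were T cells expressing Il2rb, which a lineage mix with a T cell antibody would remove; its antibodies are not given in the sources used here.

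Irf4 was not lower in the library labelled Irf4-/-. A larger B-lineage share is argued against as the whole cause, since within the larger B-like cluster the lower bound of the log2 ratio was 0.25. The mix of B cells within that cluster was not held fixed. The smaller B-like cluster had an interval of -0.0045 to 2.09. In the CD3-expressing clusters Irf4 had 212 and 102 UMIs, a log2 ratio of 1.32 with an interval of 0.97 to 1.67. An exchange of the libraries' labels cannot be told apart from correct labels, because the B-like cells of the library labelled WT held 105 Irf4 UMIs and the deleted part is not given here. Counted 3' ends outside the deleted part stay open for the same reason, with 225 UMIs in B-like cells of the library labelled Irf4-/-.

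Ifit3 and Ifit1bl1 were nearly absent from the library labelled Irf4-/-. A weaker interferon response would lower the other interferon response genes, whose median log2 ratio was 0.26. Reads moved to Ifit3b would keep the sum of Ifit3 and Ifit3b, whose log2 ratio was -2.11. The test of a variant of the locus in that mouse line took it to spare the flanking genes, which a variant need not do. An earlier form of this test, over fewer populations, went with a variant. Ifit2 had -1.03 in all kept cells but -1.80 in gamma-delta T-like cells. The interval there, -2.41 to -1.23, crossed the bound set for a flanking gene. A variant may therefore be the source but cannot be told apart from other causes. Irf4 lies on chromosome 13 and the Ifit genes on chromosome 19, so linkage to Irf4 would not account for it. An effect of the Irf4 genotype on these genes could not be separated from the line.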
